A study of Mus musculus with 15 samples.

How the data were processed

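Polyadenylated RNA was sequenced from primary myoblasts, the muscle precursor cells, of C57BL/6J mice. The cells had been treated with lipid-delivered small interfering RNA against Lmod1 (siLmod1), against Sirt1 (siSirt1) or with a control RNA (siCtrl), and were then differentiated for 1 day. Each of the 3 groups held 5 libraries, numbered 1, 2, 3, 4 and 7. The sample titles give these as replicate numbers, and each number is taken here as the same primary line in all 3 groups. Libraries were made with a TruSeq v2 kit, which keeps no strand, so a read from an antisense or overlapping transcript counts toward either gene.

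The deposited tables hold raw counts per Ensembl gene for each pair of groups, as the authors gave them. The authors also deposited TPM values, which scale transcript counts by length and library, and normalized counts, a signal equal to the raw count divided by 1 size factor per library. The values of a library were identical in the raw tables that hold it, for all 15 libraries. The normalized tables keep genes with a total over 100 counts, which left 15270, 15242 and 15292 genes in the siCtrl and siLmod1, siCtrl and siSirt1, and siLmod1 and siSirt1 tables. The authors' processing notes name DESeq2 and the mouse build mm10. The aligner, the counting tool and the annotation release are not given in the sources used here. Of the 49315 gene IDs, 48970 were paired with a symbol and 49056 had coordinates in GENCODE M21, which is on the same build. The IDs without a symbol held 0.032% of all counts. Gene lengths implied by count over TPM lay within 1% of the union exon length in M21 for 75.2% of the more abundant genes.

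Counts were read in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and models were fitted in R 4.3.3. For each pair of groups, genes with too few reads were removed with filterByExpr, library sizes were scaled by TMM, and a quasi-likelihood F test was run in edgeR 4.0.16. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 with no minimum fold change. Log2 fold changes are the first group of each comparison minus the second, with the standard error (SE) of the fit. Counts scaled to the library total (CPM) are given as the mean ± SD over the 5 libraries of a group. The floor of 3 counts lay between 0.089 and 0.143 CPM over the libraries, and it covers counting error only, since PCR copies are not independent molecules.

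The fits planned before the data were examined used the group alone, and a fit with the line number as a block was among the alternatives listed at the same time. The numbers pair the libraries, least clearly for the siSirt1 library of line 1. After each group's mean was removed, libraries of the same number in different groups correlated across 15335 genes at 0.306 to 0.908 (median 0.746, 15 pairs). Libraries of different numbers correlated at -0.531 to 0.275 (median -0.14, 60 pairs). The blocked value is therefore printed beside the value without the block, and genes are called blocked where they passed the threshold in the blocked fit. The siSirt1 library of line 1 correlated at 0.306 and 0.33 with the siCtrl and siLmod1 libraries of line 1. With those of line 3 it correlated at 0.275 and 0.217. On the third principal component it stood at 34.6, nearer to the libraries of line 3 (36.5 to 49.6) than to the other 2 of line 1 (5.91 and 6.74). Its pairing is thus uncertain, and the blocked fits of siSirt1 rest on it in part. The group-only fit had 8 residual degrees of freedom and the blocked fit had 4. The p-values speak for these 5 lines under 1 transfection per group and line.

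The levels of Lmod1 and Sirt1 were compared by an exact two-sided permutation test of the difference in mean log2 CPM over all assignments of the 10 libraries to groups of 5. The list of named genes followed a rule. It took the 10 largest changes in each direction among called genes with a mean of 5 CPM or more and with every library of the first group on 1 side of the second group's mean, leaving out predicted gene models. It added up to 4 members with the smallest p from each gene list, the 10 genes with the largest smaller fold change of the 2 among those called in opposite directions in both knockdowns with the block, and Lmod1, Sirt1, Myod1, Myog, Pax7, Myf5, Mymk, Mymx, Myh3, Cdkn1a and Mki67. The same rule was applied to the blocked fit after the data were seen.

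There were 28 gene lists, written from general knowledge of muscle cells. They were myogenic regulators; satellite cell and myoblast markers; myoblast fusion; sarcomere and contractile proteins; actin and SRF-MRTF targets; DNA replication and G1/S; mitosis and G2/M; p53 targets and growth arrest; and NF-kB and inflammatory targets. Further lists held interferon response genes, Wnt, Notch and TGF-beta pathway genes, nuclear-encoded oxidative phosphorylation, SIRT1-linked metabolic regulators, glycolysis and hypoxia, cholesterol biosynthesis, the unfolded protein and integrated stress response, extracellular matrix collagens and remodelling, and cytosolic ribosomal proteins. Markers of fibroblasts, macrophages and leukocytes, endothelium, smooth muscle and pericytes, adipocytes and Schwann cells were listed as signs of other cell types, and mitochondrially encoded and nuclear-retained transcripts as signs of RNA quality. Lists were tested with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01, adjusted by Benjamini-Hochberg over the 84 pairs of list and comparison. The tests were repeated with an estimated correlation and with fry. Members past the threshold were counted with p adjusted over all genes and adjusted over the list alone. Camera called 26 of the 84 pairs without the block and 26 with it; none of the 84 was called with an estimated correlation in either fit, and fry called 0 without the block and 12 with it.

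Agreement between the knockdowns was measured across the 14689 genes tested in both. Since both comparisons share the siCtrl libraries, the correlation, covariance and shared calls were set against 10 simulations of unchanged groups with shared controls, and against fits in which the controls or the lines were divided between the comparisons. Seed matches of the small interfering RNAs were sought without their sequences, which are not given in the sources used here. All 16384 words of 7 bases were scored in annotated 3' UTRs for a tie to lower blocked fold changes among uncalled genes, adjusted for UTR length and GC content.

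The alternatives were DESeq2 1.42.0, its size factors in edgeR, no filter on low counts, 1 fit over all 15 libraries, limma-trend on log2 TPM with a pseudocount of 1 or 0.1 for genes with a mean TPM of 1 or more, the block, and leaving out each library in turn. Added after the data were seen were the block joined with DESeq2, with DESeq2 size factors, with all 15 libraries or without 1 line, and fits without both libraries of a line. The fits were tested on simulated data in which 200 of the genes were changed, 50 at each fold. Without the block, 2-fold changes were recovered for 26%, 42% and 40% of genes in simulations of siLmod1 against siCtrl, siSirt1 against siCtrl and siSirt1 against siLmod1. With the block the shares were 76%, 86% and 76%, and 14, 8 and 9 unchanged genes were called, against 0 in each without it. Every deposited column of sample values was used. The values of some single genes are not reported here.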

Results

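RNA was measured in 15 libraries of mouse primary myoblasts after 1 day of differentiation, in 3 groups of 5 that received control, Lmod1 or Sirt1 small interfering RNA. Lmod1 encodes leiomodin 1, an actin filament nucleator, and Sirt1 encodes sirtuin 1, an NAD-dependent deacetylase. The libraries held 26097889 to 33601761 counted reads in siCtrl, 27135398 to 31829009 in siLmod1 and 21004908 to 27815744 in siSirt1. Mitochondrially encoded transcripts took 2.34 ± 0.299% of counts in siCtrl, 2.82 ± 0.428% in siLmod1 and 2.46 ± 0.4% in siSirt1 (SD, n = 5). H19, an imprinted noncoding RNA that is abundant in embryonic and differentiating muscle, had the most reads in every library, with 1.14% to 3.84% of counts. The primary line set the largest difference between libraries: the first principal component, with 42.5% of the variance over 15335 genes, placed the 3 libraries of line 4 at 111 to 113 and the other 12 between -50.8 and 0.233. The second component, with 15.3%, placed the siSirt1 library of line 7 at -95.6.

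Both targeted transcripts were lower in every line that received their own small interfering RNA. Lmod1 (ENSMUSG00000048096, mm10 chromosome 1, 135324807 to 135368065) stood at 23.17, 44.28, 35.05, 6.193 and 43.35 CPM in siCtrl lines 1, 2, 3, 4 and 7, and at 2.506, 5.469, 3.878, 1.404 and 4.246 CPM in siLmod1. In siSirt1 it stood at 8.306, 32.66, 24.52, 3.446 and 14.77 CPM, below siCtrl in 5 of 5 lines. Sirt1 (ENSMUSG00000020063, mm10 chromosome 10, 63319005 to 63381704) stood at 27.37, 17.93, 21.52, 28.38 and 36.16 CPM in siCtrl and at 4.603, 3.497, 3.493, 10.69 and 9.228 CPM in siSirt1. In siLmod1 it stood at 39.5, 28.01, 32.45, 37.52 and 54.93 CPM, above siCtrl in 5 of 5 lines. The exact two-sided permutation test gave p = 0.00794, the smallest that 5 against 5 libraries allow, for Lmod1 in siLmod1 (log2 difference -2.95, n = 5) and for Sirt1 in siSirt1 (-2.17). The same exact test gave p = 0.0476 for Sirt1 in siLmod1 (0.553) and p = 0.246 for Lmod1 in siSirt1 (-0.961).

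**Figure D1:**
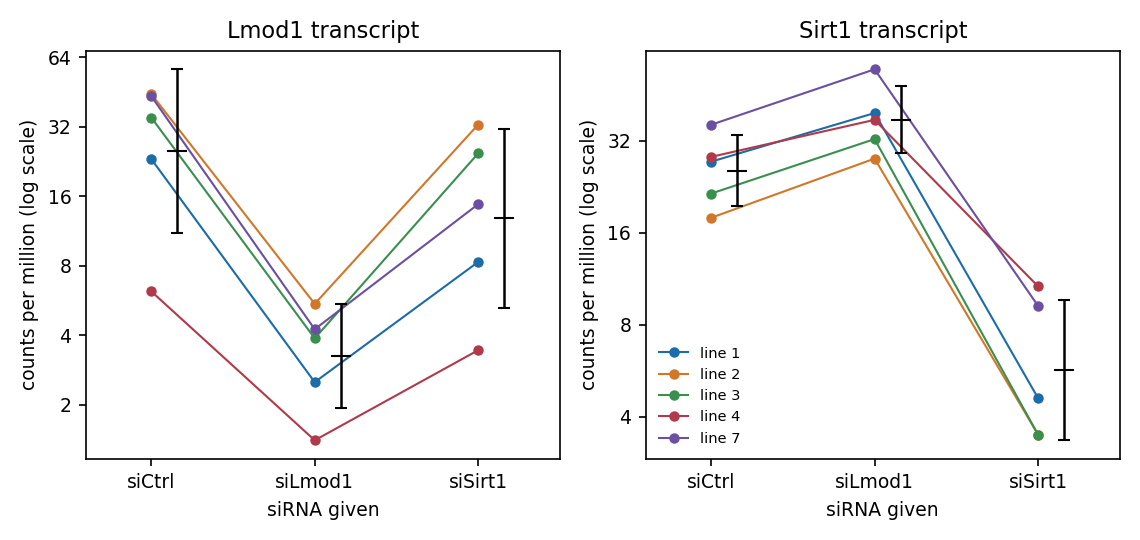
Lmod1 and Sirt1 transcript levels in each of the 15 libraries, in CPM on a log2 axis, by group; points of the same primary line are joined and the black bar gives the mean ± SD of log2 CPM (n = 5). Lmod1 lies between 1.404 and 5.469 CPM in siLmod1, and Sirt1 between 3.493 and 10.69 CPM in siSirt1.

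In edgeR's model over all genes, the same changes were called once the line was a block. Lmod1 in siLmod1 had a log2 fold change of -3.13 (SE 0.54, Benjamini-Hochberg adjusted p = 0.069), and with the block of -3.07 (adjusted p = 2.8e-06). Sirt1 in siSirt1 was at -2.06 (adjusted p = 0.073), and with the block at -2.18 (adjusted p = 0.0027). Across targets, Sirt1 in siLmod1 was at 0.54 (adjusted p = 0.51; with the block 0.54 and 0.00014), and Lmod1 in siSirt1 was at -0.86 (adjusted p = 0.72; with the block -0.96 and 0.027).

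The comparison of siLmod1 with siCtrl asked which early transcripts of differentiation depend on Lmod1. The clearest drops were in Capza1, a subunit of the protein that caps actin filaments, from 97.4 ± 16.5 to 14.4 ± 1.59 CPM, and in Erh, a small nuclear protein, from 80.9 ± 2.99 to 24.7 ± 4.14 CPM (SD, n = 5). Rac1, a GTPase that organises the actin cytoskeleton, fell from 181 ± 24.5 to 80.6 ± 19.5 CPM. With the line as a block, Myog, the transcription factor that marks commitment to differentiation, fell from 2038 ± 802 to 1441 ± 608 CPM, and Pax7, the satellite cell factor, fell too. So did 24 of 40 mitosis, 23 of 32 extracellular matrix and 8 of 13 smooth muscle genes, while 24 of 39 nuclear-encoded oxidative phosphorylation genes rose. No list was called with an estimated correlation.

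Without the block, edgeR called 17 of 15022 genes, all of them lower (1351 at an unadjusted p under 0.05). With the block it called 4430, of which 1944 were higher and 2486 lower, including all 17. With the block it called 2833 without line 1 and 1427 with all 15 libraries in 1 fit. Log2 fold changes of the named calls were -2.75 for Capza1 (ENSMUSG00000070372, mm10 chromosome 3, 104822779 to 104864505; adjusted p = 2.5e-05) and -1.71 for Erh (ENSMUSG00000021131, mm10 chromosome 12, 80634022 to 80644341; adjusted p = 0.00034). Ctns, the lysosomal cystine transporter, was at -1.31 (adjusted p = 0.029), Alg10b, a glucosyltransferase of N-glycan assembly, at -1.27 (0.0032) and Rac1 at -1.17 (0.044). Dcun1d4, Zmat3, Mcur1, Med19 and Ppp2ca followed at -1.08 to -0.83, with adjusted p between 0.013 and 0.049. Of these 10 lower genes, 8 carried in their 3' UTRs a word of 7 bases that was tied to lower expression in siLmod1, and Erh and Ppp2ca did not.

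With the line as a block, the genes named by the rule included Igfn1 (1.71), a sarcomere-associated protein of skeletal muscle, and Ppp1r27 (1.18) upward, and downward, besides Lmod1, Capza1 and Erh, Heg1 (-1.77), Aqp1 (-1.77), Myl9 (-1.57) and Cav1 (-1.56). Of the 10 lower genes that the rule named with the block, 7 carried in their 3' UTRs a word tied to lower expression in siLmod1. Blocked log2 fold changes of the regulators of differentiation were -0.50 for Myog (adjusted p = 0.00017), -0.79 for Pax7 (0.00018) and -0.36 for Mymk, the membrane protein myomaker that drives fusion (0.0012). Myod1 was at 0.04 (adjusted p = 0.67), Myf5 at -0.03 (0.91), Mymx at -0.06 (0.71) and Myh3, the embryonic myosin heavy chain, at -0.18 (0.12). Cdkn1a, the cell cycle inhibitor p21, fell by 0.31 (adjusted p = 0.0012). None of these passed without the block.

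Of 40 mitosis and G2/M genes, 24 fell with the block and none rose (0 without the block; 33 with p adjusted over the list alone), with a median of -0.60, Kif23, a kinesin of cytokinesis, at -1.06, Mki67 at -0.88 and the mitotic transcription factor Foxm1 at -0.81. Camera called the list at an adjusted p of 2.1e-06 without the block and 2.4e-07 with it, and not with an estimated correlation (adjusted p = 0.694 with an estimated correlation and the block). The median lay below 0 in 5 of 5 lines, from -0.0794 in line 3 to -1.28 in line 7. Of 37 DNA replication and G1/S genes 2 rose and 6 fell (1 and 4 adjusted over the list alone; camera adjusted p = 0.0175 without the block, 0.0517 with it, and adjusted p = 0.815 with an estimated correlation). Ccnd1, which encodes cyclin D1, fell by 1.54 with the block.

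Of 32 extracellular matrix genes, 23 fell and 0 rose with the block (24 adjusted over the list alone), with a median of -0.70, among them Fbn1, the fibrillin of elastic microfibrils, at -1.24, the collagen Col8a1 at -1.23 and the protease inhibitor Timp2 at -0.45 (camera adjusted p = 2.1e-05 without and 4.3e-11 with the block, and adjusted p = 0.644 with an estimated correlation). Col1a1, the main collagen of connective tissue, was at 0.357 against 2.82 CPM, with a blocked log2 fold change of -2.48 (adjusted p = 0.02) and a lower value in 4 of 5 lines. The fibroblast markers had 2 of 7 lower with the block (2 adjusted over the list alone) and a median of -0.25. Of 13 smooth muscle and pericyte markers 8 fell (8 adjusted over the list alone), with a median of -0.72, among them the ATP-sensitive potassium channel subunit Abcc9 at -1.18, Itga8 at -1.18, Notch3 at -1.04 and Mcam at -0.74 (camera adjusted p = 0.018 and 9.9e-05, and adjusted p = 0.518 with an estimated correlation). A seed word was carried by 5 of its 8 members whose 3' UTR was searched. These 5 had a median of -0.16, and the 3 without a word -0.66. Of 9 Schwann and glial markers 3 fell (5 adjusted over the list alone), with a median of -0.29 (camera adjusted p = 0.0353 without and 0.0592 with the block, and adjusted p = 0.688 with an estimated correlation). Of 31 actin and SRF-MRTF targets 14 fell and 4 rose (17 and 4 adjusted over the list alone), with Tagln2 at -1.43 (camera adjusted p = 0.0545 without and 8.2e-05 with the block, and adjusted p = 0.694 with an estimated correlation).

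Sarcomere transcripts went both ways: of 54 members 8 rose and 18 fell with the block (8 and 22 adjusted over the list alone), with Myl1 at 0.71, Klhl41 at 0.71, Lmod2, a leiomodin of striated muscle, at 0.60 and Myh1 at -0.45. Camera did not call the list (adjusted p = 0.655 without and 0.0734 with the block). Of 23 fusion genes 10 fell and 0 rose (10 adjusted over the list alone), among them Nfatc2 at -0.81, Ehd1 at -0.40 and the tetraspanin Cd81 at -0.25 (camera adjusted p = 0.0672 without and 0.0142 with the block, and adjusted p = 0.55 with an estimated correlation). Of 20 Notch genes 9 fell and 2 rose (11 and 2 adjusted over the list alone), with Hes1 at -0.85 and Notch1 at -0.76 (camera adjusted p = 0.0441 and 0.0131, and adjusted p = 0.688 with an estimated correlation).

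Of 39 nuclear-encoded oxidative phosphorylation genes 24 rose and 0 fell with the block (27 adjusted over the list alone), with a median of 0.18, Cox7c at 0.32 and Uqcrfs1 at 0.28 (camera adjusted p = 2.0e-07 and 1.5e-06, and adjusted p = 0.694 with an estimated correlation). Of 13 mitochondrially encoded transcripts, listed as a sign of RNA quality, 2 rose (2 adjusted over the list alone), with a median of 0.17 (camera adjusted p = 0.0198 without and 0.0674 with the block, and adjusted p = 0.789 with an estimated correlation). Of 31 glycolysis and hypoxia genes 4 rose and 5 fell (4 and 5 adjusted over the list alone), with a median of 0.0166 (camera adjusted p = 0.982 without and 0.668 with the block). Of 32 SIRT1-linked metabolic regulators 13 rose and 2 fell (14 and 3 adjusted over the list alone), including Cpt1a, which admits fatty acids to mitochondria, at 0.55, and the mitochondrial deacetylase Sirt3 at 0.39 (camera adjusted p = 0.0355 and 0.0037, and adjusted p = 0.518 with an estimated correlation). Of 35 cytosolic ribosomal protein genes 23 fell and 0 rose (27 adjusted over the list alone), with Rplp1 at -0.52 and Rps19 at -0.30 (camera adjusted p = 7.9e-06 and 6.6e-05, and adjusted p = 0.714 with an estimated correlation); reads of ribosomal protein genes can be shared with pseudogenes. Of 24 p53 targets 13 fell and 2 rose (16 and 2 adjusted over the list alone), with Aen at -0.51 and Phlda3 at -0.42 (camera adjusted p = 2.5e-05 in both fits, and adjusted p = 0.688 with an estimated correlation). Leaving out any 1 of the 10 libraries left 3 to 10 calls without the block, and DESeq2 without the block called 261.

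The comparison of siSirt1 with siCtrl asked which early transcripts depend on Sirt1. Ogn, which encodes osteoglycin, a matrix proteoglycan, fell from 251 ± 55.1 to 70.9 ± 25.9 CPM, and Stk40, a kinase-like protein, rose from 20.9 ± 4.25 to 53.3 ± 11.9 CPM (SD, n = 5). With the block, 14 of 54 sarcomere genes fell, among them Tcap, the titin cap of the Z-disc, and the list's median was lowest in lines 4 and 7. With it 10 of 28 genes of the unfolded protein and integrated stress response rose, and their list's median was above 0 in 5 of 5 lines. No list was called with an estimated correlation.

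Without the block, edgeR called 19 of 14912 genes, 2 higher and 17 lower (1440 at an unadjusted p under 0.05). With the block it called 1054, of which 406 were higher and 648 lower, including all 19. With the block and all 15 libraries in 1 fit it called 2530, more than the 1427 in siLmod1. The higher genes were Stk40 (ENSMUSG00000042608, mm10 chromosome 4, 126103957 to 126141029; log2 fold change 1.35, adjusted p = 0.042) and Prr14l (0.75, adjusted p = 0.036). Among the lower ones were Ogn (-1.82, adjusted p = 0.042), the endoplasmic reticulum oxidoreductase Tmx1 (-1.39, 0.045), Fam98a (ENSMUSG00000002017, mm10 chromosome 17, 75537086 to 75551946; -1.35, 0.00033) and Klhl20, a ubiquitin ligase adaptor (-1.19, 0.0041). Blzf1, a Golgi protein, was at -1.18, Chchd3, which shapes mitochondrial cristae, at -1.14, and Prkar2a, a regulatory subunit of protein kinase A, at -1.08. Rprd1a, the heat shock factor Hsf2 and Carnmt1 followed at -0.99 to -0.93. Of these 10 lower genes, 8 carried in their 3' UTRs a word tied to lower expression in siSirt1, and Blzf1 and Chchd3 did not.

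With the line as a block, the genes named by the rule included Foxred2 (1.66), Lfng (1.42), a glycosyltransferase that modifies Notch and that differed by 2.81 in line 4 against 0.82 to 1.35 in the others, and the apoptosis regulator Bcl2l11 (1.32) upward, and Mfap4 (-2.92), Adamtsl2 (-2.70) and Srl, which encodes sarcalumenin of the sarcoplasmic reticulum (-2.24), downward. Of the 10 lower genes that the rule named with the block, 4 carried a word tied to lower expression in siSirt1. Blocked values of the regulators of differentiation were 0.13 for Myod1 (adjusted p = 0.49), -0.34 for Myog (0.28), 0.34 for Pax7 (0.3), -0.22 for Myf5, 0.22 for Mymx and -0.66 for Myh3 (0.052), while Mymk fell by 0.54 (0.032) and Cdkn1a by 0.76 (0.014). Neither Mymk nor Cdkn1a passed without the block.

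Of 54 sarcomere genes, 14 fell and 0 rose with the block (0 without it; 34 adjusted over the list alone with the block), with a median of -0.61. Casq1, the calcium store protein of the sarcoplasmic reticulum, was at -2.22, Tcap at -2.0 and Acta1, skeletal actin, at -0.88; Mylk2 was at -0.88 and did not pass (adjusted p = 0.059). Camera called the list at an adjusted p of 5.3e-10 without and 3.9e-20 with the block (adjusted p = 0.688 with an estimated correlation). The list's median by line was -0.534, -0.241, -0.0314, -1.16 and -1.2 in lines 1, 2, 3, 4 and 7. Lines 4 and 7 hold the libraries that stood apart on the first 2 principal components. Of 31 glycolysis and hypoxia genes 1 rose and 2 fell (1 and 4 adjusted over the list alone), with the oxygen sensor Egln3 at -1.50 and Ddit4 at -0.85 (camera adjusted p = 0.0096 and 0.0208, and adjusted p = 0.815 with an estimated correlation). This list was also lowest in lines 4 and 7, at -1.18 and -0.633.

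Of 28 genes of the unfolded protein and integrated stress response 10 rose and 0 fell with the block (15 adjusted over the list alone), with a median of 0.45 and line medians from 0.317 to 0.566. The kinase-like Trib3 was at 1.05, the stress transcription factor Ddit3 at 0.80, Sesn2 at 0.56 and Herpud1, of the degradation machinery of the endoplasmic reticulum, at 0.49. Camera called the list at an adjusted p of 2.1e-05 without and 7.9e-11 with the block (adjusted p = 0.118 with an estimated correlation and the block), and fry called it with the block (adjusted p = 0.0088).

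Camera called the mitosis and G2/M list lower (adjusted p = 0.00092 and 9.2e-05, and adjusted p = 0.806 with an estimated correlation), but 0 of 40 members passed, Ccnb2 was at -1.04 (adjusted p = 0.077) and Mki67 at -0.21 (0.78), and the median of -1.91 in line 1 lay apart from -0.459 to 0.106 in the others. The line 1 value rests on the uncertain pairing of its siSirt1 library. Without the siCtrl library of line 7 the list's median was 0.03. Of 39 oxidative phosphorylation genes 1 fell and 0 rose with the block (0 adjusted over the list alone), with a median of -0.19 (camera adjusted p = 6.2e-05 and 0.00022, and adjusted p = 0.789 with an estimated correlation). Over 11 scaling settings this median ranged from -0.198 to -0.0514. Of 24 p53 targets 5 fell and 1 rose (9 and 2 adjusted over the list alone), with Eda2r at -0.93 (camera adjusted p = 0.0365 and 0.0318, and adjusted p = 0.688 with an estimated correlation). A seed word was carried by 10 of these targets, and without them the list's blocked median was 0.0168, against -0.1386 with them. Of 31 actin and SRF-MRTF targets 6 fell and 1 rose (7 and 1 adjusted over the list alone), with Myl9 at -1.33 and Acta2 at -0.82 (camera adjusted p = 0.0282 and 0.00067, and adjusted p = 0.688 with an estimated correlation).

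Among markers of other cell types, 3 of 13 smooth muscle markers fell (3 adjusted over the list alone), Abcc9 at -1.31, Tagln at -0.91 and Acta2 (camera adjusted p = 0.18 without and 0.0223 with the block, and adjusted p = 0.688 with an estimated correlation). Of 10 adipocyte markers 2 rose (3 higher and 1 lower adjusted over the list alone), with Pparg, the regulator of fat cell formation, at 1.57 (camera adjusted p = 0.182 and 0.0085, and adjusted p = 0.556 with an estimated correlation). Of 8 fibroblast markers 1 rose, the proteoglycan Dcn at 1.85 from a level of 0.292 CPM in siCtrl, and 1 fell, Mfap4 (1 and 1 adjusted over the list alone). Leaving out 1 library at a time left 3 to 9 calls without the block, and 13 without the siSirt1 library of line 2. Without the siSirt1 and siCtrl libraries of line 4, or of line 7, 5 and 1 genes were called without the block. With the block, 332, 411, 398, 525 and 580 genes were called without line 1, 2, 3, 4 or 7.

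The comparison of siSirt1 with siLmod1 asked how the knockdowns differ. Capza1 and Erh were higher in siSirt1, and Ogn, Tgm2, a crosslinking transglutaminase, and Mb, the oxygen-binding myoglobin of muscle, were lower, with Mb at 121 ± 42.4 against 448 ± 94.8 CPM (SD, n = 5). With the block, 15 of 39 oxidative phosphorylation and 14 of 53 sarcomere genes were lower in siSirt1 than in siLmod1. In turn 10 of 28 stress response, 7 of 20 Notch and 6 of 35 ribosomal protein genes were higher. No list was called with an estimated correlation.

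Without the block, edgeR called 229 of 14998 genes, 102 higher in siSirt1 and 127 lower (2475 at an unadjusted p under 0.05). With the block it called 2379, 1115 higher and 1264 lower, including all 229. With the block it called 1042, 1771, 946, 1395 and 1662 without line 1, 2, 3, 4 or 7, and 4210 with all 15 libraries in 1 fit. Of the calls on log2 TPM with a pseudocount of 1, 106 were higher and 76 lower, so that 58.2% were higher against 44.5% of the calls on counts. The largest increases under the naming rule were in Capza1 (log2 fold change 2.40, adjusted p = 0.00011), Ftl1 (2.00, 0.018), the ribosome-binding protein Rrbp1 (1.77, 0.013), the drug exporter Abcb1b (1.58) and Tubb3 (1.53), with Erh at 1.51 (0.00094). Glipr2, Ctns, Ggta1 and Asap1 followed at 1.49 to 1.44. The largest decreases under it were in Tgm2 (ENSMUSG00000037820, mm10 chromosome 2, 158116402 to 158146436; -2.67, adjusted p = 0.017), Sirt1 itself (-2.62, 0.0099), Ppp1r27 (-2.37, 0.0091), Ogn (-2.29, 0.0076) and the lipid transporter Mfsd2a (-2.10). Mb was at -1.89 (0.0099), Prkar2a at -1.82 (0.00013), Hist1h2be at -1.74, Otud1 at -1.61 and Blzf1 at -1.57 (0.00013). Of these 10 lower genes, 4 carried in their 3' UTRs a word tied to lower expression in siSirt1 against siLmod1. Ftl1 and Hist1h2be have close family members or pseudogenes, so their reads can be shared.

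Of 39 oxidative phosphorylation genes 15 were lower in siSirt1 and 0 higher with the block (30 adjusted over the list alone; 0 without the block), with a median of -0.39 and Ndufv1 at -0.45 (camera adjusted p = 1.1e-11 and 1.2e-09, and adjusted p = 0.694 with an estimated correlation). The 13 mitochondrially encoded transcripts had a median of -0.33 and no member passed (camera adjusted p = 0.0171 without and 0.0592 with the block, and adjusted p = 0.815 with an estimated correlation). Of 53 sarcomere genes 14 were lower and 0 higher (22 adjusted over the list alone), with Tcap at -1.83, Lmod2 at -1.23 and the intermediate filament Des at -0.61 (camera adjusted p = 2.4e-06 and 7.9e-11, and adjusted p = 0.694 with an estimated correlation). The sarcomere median was -1.12 in line 4 and -1.13 in line 7, and 0.0718 in line 3. Of 31 glycolysis and hypoxia genes 5 were lower and 2 higher (5 and 2 adjusted over the list alone; camera adjusted p = 0.0273 and 0.0212, and adjusted p = 0.815 with an estimated correlation), with a median of -0.925 in line 4 and -0.642 in line 7.

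Of 28 stress response genes 10 were higher and 0 lower with the block (12 adjusted over the list alone), with Manf at 0.62, Sesn2 at 0.75 and Pdia6, a protein disulfide isomerase, at 1.15 and also called without the block (adjusted p = 0.035). Camera called the list in both fits (adjusted p = 0.00044 and 9.7e-06, and adjusted p = 0.688 with an estimated correlation). Of 20 Notch genes 7 were higher and 0 lower (9 adjusted over the list alone), with the receptors Notch3 at 1.31 and Notch2 at 0.62 and the regulator Dtx4 at 0.89 (camera adjusted p = 0.0061 and 9.2e-05, and adjusted p = 0.518 with an estimated correlation). Of 32 extracellular matrix genes 7 were higher and 1 lower (10 and 2 adjusted over the list alone), with the collagens Col12a1 at 1.45 and Col3a1 at 1.12 (camera adjusted p = 0.0492 and 0.004, and adjusted p = 0.694 with an estimated correlation). Of 35 ribosomal protein genes 6 were higher and 0 lower (6 adjusted over the list alone), with Rplp1 at 0.62 and also called without the block (camera adjusted p = 0.00022 and 0.00046, and adjusted p = 0.694 with an estimated correlation).

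With the block, Pax7 was higher in siSirt1 by 1.11 (adjusted p = 0.008), Lmod1 by 2.04 (0.0024) and Ccnd1 by 2.50 (0.02), and Cdkn1a was lower, at -0.47 (0.029). Myod1, Myog, Myf5, Mymk, Mymx, Myh3 and Mki67 did not pass in either fit. Leaving out 1 library at a time left 54 to 134 calls without the block, and 247 without the siSirt1 library of line 2; DESeq2 without the block called 922.

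**Figure D2:**
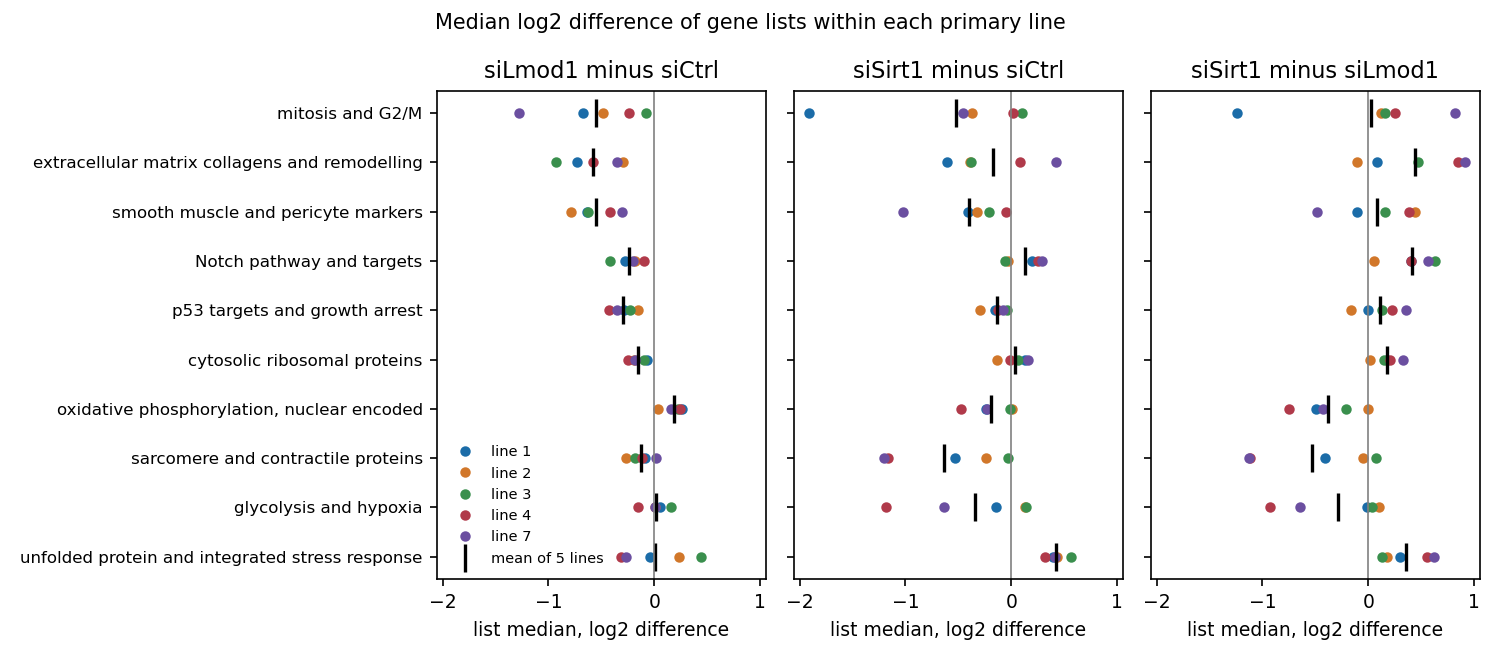
Median log2 difference of the members of 10 gene lists within each primary line, in 3 panels, 1 per comparison; each point is 1 line and the black tick is the mean of the 5 lines. The extracellular matrix list lies below 0 in all 5 lines in siLmod1, the stress response list above 0 in all 5 lines in siSirt1, and the sarcomere list reaches -1.16 and -1.2 in lines 4 and 7 in siSirt1.

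Both knockdowns were compared with each other because the study looked for effectors downstream of Lmod1 and Sirt1. Mcur1, a regulator of mitochondrial calcium uptake, was the 1 gene called lower in both without the block, at -0.93 in siLmod1 (adjusted p = 0.013) and -0.84 in siSirt1 (0.031); it stands outside the naming rule in siSirt1 and was chosen after its values were seen. Its 3' UTR carried a seed word of each knockdown. Without the block it was not called in both when the libraries of any 1 line number were left out. With the block it was called in both in each of these 5 fits. With the block, 366 genes were called in the same direction, 141 higher and 225 lower. Another 128 were called in opposite directions. Lower in both were Myl9 (-1.57 and -1.33) and Abcc9 (-1.18 and -1.31), and Cpt1a was higher in both (0.55 and 0.79).

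Genes that moved in opposite directions with the block included Tgm2, at 0.89 in siLmod1 and -1.96 in siSirt1, and Prkar2a, at 0.73 and -1.08. Fech, the last enzyme of haem synthesis, was at 0.78 and -0.65, the urate transporter Slc2a9 at -1.30 and 1.84, and the carboxylesterase Ces2g at -1.83 and 1.73. Sirt1 itself was among them, at 0.54 and -2.18. Prkar2a and Fech each carried in the 3' UTR a word tied to lower expression in siSirt1, so their falls there may be off-target. Of the opposite calls 86 were higher in siLmod1 and lower in siSirt1, and 42 the reverse.

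Across the 14689 genes tested in both, the log2 fold changes correlated at r = 0.196 without the block and 0.200 with it. Simulations with shared controls, line differences and no group effect gave 0.4997 and 0.506. Changes that the knockdowns do not share lower r, so the lower measured r does not show less agreement than the shared controls give. Genes are not independent replicates. The shared siCtrl libraries alone gave a covariance of 0.0307 in simulations without the block, against 0.0306 measured. The simulations gave every group the same spread per gene, fitted over all 15 libraries. A wider spread in 1 group would therefore raise the simulated covariance. These values cannot decide whether the knockdowns agree beyond the shared controls. With the block the measured covariance was 0.0307 against 0.0273 simulated. The numbers of genes called in each comparison would give 161.4 same-direction and 151.6 opposite calls if they were independent. When the lines were divided so that each comparison used its own controls, r with the block was 0.097 (range -0.0036 to 0.17) and the covariance 0.0199 (-0.00087 to 0.032). Over the 20 divisions the medians were 5.5 same-direction (0 to 495) and 0.5 opposite calls (0 to 304).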

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

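Chosen after the results were seen were the tests of several seed words, of the fibroblast share, of line 7 alone and of the muscle cell share, and the patterns they bear on are hypotheses. Among 215 groups of 5 values tested for a value that stood apart from the others, 8 were found where chance gives about 11, and 5 of the 8 were in line 4.

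The siCtrl library of line 3 had 15744 genes with 10 or more counts, against 14814 to 14988 in the other siCtrl libraries. The log2 difference of Lmod1 between siLmod1 and siCtrl was -2.09 in line 4, against -3.33 to -3.00 in the other lines, and Lmod1 stood at 6.193 CPM in the siCtrl library of that line. Ctns differed by -0.979 between siLmod1 and siCtrl in line 2, against -1.40 to -1.34 elsewhere. In line 4, Blzf1 differed by -1.61 between siSirt1 and siCtrl, against -1.13 to -0.942, and by -1.78 between siSirt1 and siLmod1, against -1.56 to -1.47. Lfng differed by 2.81 between siSirt1 and siCtrl in line 4, against 0.82 to 1.35. Ppp1r27 differed by -3.64 between siSirt1 and siLmod1 in line 4, against -2.28 to -1.77. The median of the mitosis and G2/M list differed by -1.91 between siSirt1 and siCtrl in line 1, whose pairing is uncertain, against -0.459 to 0.106.

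Some of the genes lower in each knockdown may be direct off-targets of the small interfering RNA through seed matches in their 3' UTRs. In siLmod1 the word most tied to lower expression among uncalled genes, TGAACCT, was carried by 10 of the 16 searched genes called lower, 62.5% against 11.6% of uncalled genes (one-sided Fisher exact p = 1.9e-06), and at least 1 of 4 such words by 12 of the 16, 75.0% against 22.7% (p = 1.4e-05 by the same test). In siSirt1 the top word, GTGAATA, was no more common in lower genes, at 5.9% against 10.2% (one-sided Fisher exact p = 0.84), but at least 1 of 3 words was carried by 13 of 17, 76.5% against 22.7% (one-sided Fisher exact p = 3.9e-06). In siSirt1 against siLmod1, CATATAC or GAATAAA was carried by 62 of 118 searched lower genes, 52.5% against 26.6% (one-sided Fisher exact p = 2.7e-09). GAATAAA was carried by 47 of the 118, and it does not occur in annotated transcripts of Sirt1. In this comparison the top word, CATATAC, had t = -8.3, against 8.0 for TTTTATA, the word most tied to higher values. Words tied to lower values thus hardly stood out, and this result is weaker ground for off-targets. There TGAACCT, the top word of siLmod1, was among those most tied to higher values (t = 5.8), so calls in either direction may hold off-targets. Over all searched genes lower in the blocked fit the shares were smaller, 680 of 2012 in siLmod1 and 268 of 602 in siSirt1, against 1299 of 6181 and 1945 of 9038 uncalled genes, and these are no separate test, since the words were chosen on fold changes that included most of these genes. Without the sequences of the small interfering RNAs it stays open which lower genes depend on Lmod1 or Sirt1 themselves, and genes without a word, such as Erh, Ppp2ca, Blzf1 and Chchd3, may also be off-targets that the word search missed.

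The lower extracellular matrix transcripts in siLmod1 may follow from loss of Lmod1, but technical explanations other than those tested remain. Without the genes that carry a seed word, the list's median was -0.552 over its 25 remaining searched members, against -0.696, which argues against direct seed matches as the whole cause. Line 4 alone does not account for it, since the mean over the other 4 lines was -0.578 against -0.577 over all 5. The median of the fibroblast markers lay above that of the matrix list by 0.392 (SE 0.0618 over the 5 lines), but was below 0 in 4 of 5 lines. Only 3 of the 7 markers passed the 5 CPM and 3' UTR limits of the word search. The most abundant of them, Serpinf1 and Gsn at 374 and 292 CPM in siCtrl, are also expressed by muscle cells. The markers therefore cannot decide whether the share of fibroblasts fell. A lower share of smooth muscle, pericyte or Schwann cells stays open, since the line means of these lists were -0.554 and -0.384, below 0 in 5 of 5 lines, although their most abundant markers, Acta2 and Erbb3 at 4539 and 385 CPM in siCtrl, are also expressed by muscle cells, and indirect off-target effects stay open too.

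The lower sarcomere transcripts in siSirt1 may reflect slower differentiation, most of all in lines 4 and 7. Without the genes that carry a seed word the list's median was -0.601 over 47 members, against -0.612, which argues against direct seed matches as the cause. Without line 7, whose siSirt1 library stood apart, the mean of the line medians was -0.492, against -0.633, and the median was below 0 in each of the other 4 lines. That mean still holds line 4, at -1.16, while lines 1, 2 and 3 were at -0.534, -0.241 and -0.0314. Lines 4 and 7 were not left out together, so this test cannot decide whether they hold most of the fall. A lower share of muscle cells would raise the markers of other cell types alike. The adipocyte list, led by Acsl1 at 60.5 CPM in siCtrl, lay above the endothelial list by 0.87 (SE 0.199 over the 5 lines). The endothelial list was led by Tek at 21.2 CPM, and only 2 of its 6 members passed the 5 CPM and 3' UTR limits of the word search. A change in adipogenic cells could also part the 2 lists, so their gap cannot decide whether the share of muscle cells fell, and both stay open. Indirect off-target effects and differences in the timing of differentiation between cultures stay open.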

How the results depend on the processing

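The fits joined with the block, those without both libraries of a line and the division of the lines were chosen after the data were seen. Of 45 gene results past the threshold without the block, 905 of 1350 pairs of result and alternative stayed on the same side of it, 445 fell short with the same direction and 0 reversed. Of 122 named gene results that did not pass, 2746 of 3650 stayed, 868 passed and 36 reversed. Of 26 list results that passed, 260 of 364 stayed, 103 fell short and 1 reversed; of 4 that did not, 38 of 56 stayed and 18 passed. The cause was not tested for any of the changes below. Calls in siLmod1 against siCtrl were 17, with the block 4430, with DESeq2 261, with no filter 6 and with all 15 libraries 38, and with the block and all libraries 1427. Calls in siSirt1 against siCtrl were 19, with the block 1054, with DESeq2 294, with no filter 7, with all libraries 150, and on log2 TPM 2 with either pseudocount; joined with the block, all libraries gave 2530 and DESeq2 1940. Calls in siSirt1 against siLmod1 were 229, with the block 2379, with DESeq2 922, with no filter 90 and with all libraries 554, and with the block and all libraries 4210. Leaving out a library or both libraries of a line gave 2 to 19, 1 to 13 and 7 to 247 calls in these comparisons without the block, and 2833 to 4264, 332 to 580 and 946 to 1771 with it. The median log2 fold change of all genes in siSirt1 against siCtrl was 0.1231 or 0.1338 on TPM (pseudocount 1 or 0.1), against 0.01939 on counts.

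The correlation between the knockdowns was 0.196; with DESeq2 it was 0.401, with no filter 0.466, with DESeq2 and the block 0.376, with the controls divided -0.271, with the lines divided and the block 0.0967, and without 1 line number 0.18 to 0.234. Dividing the controls sets different lines against each other. Genes called in both in the same direction numbered 1, with DESeq2 15, with no filter, with divided controls or without any 1 line number 0, and with the block 366; joined with the block, DESeq2 gave 592, all libraries 325 and divided lines a median of 5.5. In opposite directions there were 0, with DESeq2 5, with all libraries 1 and with the block 128; joined with the block, DESeq2 gave 241, all libraries 101 and divided lines 0.5. List tests past the threshold numbered 26 in either fit, 0 with an estimated correlation in either fit, 0 with fry and 12 with fry and the block, and 16 to 29 when a library was left out; 16 was without the siCtrl library of line 7. No list past the threshold changed the sign of its median over 11 scaling settings, but some sizes moved. In siSirt1 against siCtrl the median ranged from -0.144 to -0.000444 for p53 targets and from -0.198 to -0.0514 for oxidative phosphorylation. In siLmod1 against siCtrl it ranged from -0.724 to -0.289 for smooth muscle and pericyte markers.

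Among genes that did not pass without the block, some log2 fold changes turned when a library or line was left out. In siLmod1 against siCtrl, Myod1 ranged from -0.0476 to 0.12, Myf5 from -1.51 to 1.45, Mymx from -0.86 to 0.64 and Myh3 from -0.55 to 0.0632, and Mymx was at 0.0078 and 0.0099 on log2 TPM with a pseudocount of 1 and 0.1. In siSirt1 against siCtrl, Myf5 ranged from -1.62 to 1.195, Mymx from -0.44 to 0.99, Mki67 from -1.065 to 0.49 and the mitosis and G2/M list from -0.9958 to 0.02674, the latter without the siCtrl library of line 7. In siSirt1 against siLmod1, Myod1 ranged from -0.01555 to 0.13, Myf5 from -1.34 to 0.95, Mymk from -0.39 to 0.15 and Mymx from -0.34 to 1.08. At this depth and number of lines, the fit without the block recovered 4% to 6% of simulated 1.5-fold changes and the blocked fit 34% to 62%.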

Other observations

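Among the tests in this part, the sets of several seed words were chosen after the first result was seen. Of 18 satellite cell and myoblast markers, 3 rose and 7 fell with the block in siLmod1 (4 and 7 adjusted over the list alone), with a median of -0.22 and a median below 0 in 5 of 5 lines (-0.3 to -0.202), and camera did not call the list (adjusted p = 0.102 without and 0.141 with the block). Of its 15 members searched in siLmod1, the 6 with a seed word had a blocked median of -0.543 and the 9 without one -0.0508. In siSirt1 2 rose and 3 fell, with the FGF signalling inhibitor Spry1 at -1.52 and the adhesion molecule Ncam1 at -0.67, and a list median of 0.06. Of 24 myogenic regulators 3 rose and 7 fell in siLmod1 (median 0.02) and 1 rose and 3 fell in siSirt1 (median -0.18), and neither list test passed in any comparison. The test with the block pointed down while the median was above 0 for the satellite cell list in siSirt1 and for the myogenic regulators in siLmod1, whose mean was -0.08. Of 23 fusion genes 5 fell and 0 rose in siSirt1 with the block, among them the junction molecule Jam2 at -1.25 and Cd81 at -0.59 (camera adjusted p = 0.0517 with the block). In siSirt1, the Notch ligand Dll1 was at 0.69 with 2 of 20 Notch genes higher (camera adjusted p = 0.0896 with the block), and Txnip, a regulator of glucose uptake, at 1.06 and Cpt1a at 0.79 with 3 of 33 SIRT1-linked regulators higher (camera adjusted p = 0.376; the list's median was -0.02 and its mean 0.13). Of 32 extracellular matrix genes 3 fell and 1 rose in siSirt1 with the block (3 and 1 adjusted over the list alone): the crosslinkers Loxl1 and Lox, at -1.27 and -1.21, and Sparc, at -0.67, fell, and a collagen outside the naming rule rose by 0.60. The list's median was -0.21 (camera adjusted p = 0.277).

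Camera called the 8 lists of the next 2 sentences in no comparison. Blocked medians in siLmod1, siSirt1 and siSirt1 against siLmod1 were 0.01, 0.10 and 0.20 for NF-kB and inflammatory targets, 0.11, 0.10 and 0.00 for interferon response, -0.18, 0.00 and 0.09 for Wnt, and -0.16, -0.11 and -0.02 for TGF-beta and BMP targets. They were 0.06, -0.16 and -0.19 for cholesterol biosynthesis, -0.05, -0.05 and 0.16 for macrophage and leukocyte markers, -0.14, -0.43 and -0.40 for endothelial markers, and -0.08, 0.14 and 0.42 for nuclear-retained RNA. The median of the mitochondrially encoded transcripts in siSirt1 was -0.15 and that of the ribosomal protein transcripts 0.02, and camera called neither list in that comparison.

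Other splits of the 10 libraries of each comparison into 5 and 5 were fitted in the same way. Of 100 splits drawn from 126, the real one included, 1 gave as many calls as the real 17 in siLmod1 against siCtrl, and the highest other split gave 0. For siSirt1 against siCtrl it was 1 of 100, with 19 calls against at most 1, and for siSirt1 against siLmod1 1 of 100, with 229 against at most 1. These draws ignore the lines: only 9 of the 100 part the pair of every line, and the others part 1 or 3 lines, which puts differences between lines into the groups. With the block, 16 splits part the pair of every line, which is too few for a share under 0.05. The real split, 1 of the 16, gave 4430, 1054 and 2379 calls and the highest other gave 0 in each. In every other split, blocked or not, each group mixes libraries of both treatments, and their difference widens the spread within groups. Few calls are likely there whatever the rate of false calls, so the contrast cannot decide how many of the real calls are false.

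The words of 7 bases tied to lower expression were TGAACCT, GACGAAT, TCCCCCC and CGGTAAC in siLmod1 and GTGAATA, CATATAC and CTCACTA in siSirt1. All but TCCCCCC occur in annotated transcripts of the gene that was targeted, where 18.8% of all 16384 words occur for Lmod1 and 24.8% for Sirt1. The top words had t = -9.7 in siLmod1 and -10.5 in siSirt1, against 4.8 and 5.7 for the words most tied to higher expression. In siSirt1 against siLmod1 the words were CATATAC and GAATAAA, and the top word had t = -8.3 against 8.0.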
